A study of Arabidopsis thaliana with 12 samples.

How the data were processed

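RNA was measured by sequencing in whole 7-day-old Arabidopsis thaliana seedlings of the wild type Col-0 (wt) and of a line labelled as the hop1 hop2 hop3 triple mutant (hop). Seedlings were kept under control conditions or held at 38 °C for the last 3 h. The 12 libraries form 4 groups of 3 replicates, assigned from the labels alone. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

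Libraries were made with a stranded mRNA kit, per the labels' protocols. TopHat2 2.1.0, HTSeq and DESeq2 1.1.14 are named in the submitters' processing notes, without role or order. The genome build, the annotation and any filter were not given in the sources used here. The authors deposited 1 table of 32833 genes. Its expression signal is a fragment count per gene divided by 1 size factor per library, headed as normalized fragments per the file headers. The authors also deposited log2 fold changes between groups, per the file headers from DESeq2. The adjusted p-values of those comparisons were deposited by the authors beside them. Neither of these 2 columns entered a test here, and they are quoted only as the authors' deposited table.

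Dividing every value by the value of 1 fragment gave whole numbers for 100% of values within a tolerance of 0.01, so the fragment counts and library depths could be recovered. Libraries held 26.1 to 38.7 M fragments. A count of 3 fragments over a group of 3 libraries corresponds to a mean normalized count of 0.728 in wt control, 1.42 in wt heat, 0.727 in hop control and 1.24 in hop heat. That value served as the floor for genes at 0 in a whole group, and such floors cover counting error only. The name of the deposited table calls it stranded, but the counting settings are not otherwise given. Antisense and overlapping genes, and genes with near-identical copies, therefore carry some uncertainty of assignment.

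The design assumed raw counts. Because the table holds normalized values, the test used was limma 3.58.1 (trend and robust options, R 4.3.3) on log2(value + 1), the test the design named for this case. All 12 libraries entered 1 fit with 4 group means. Genes with a value of at least 1 in at least 3 samples were tested, which left 23827. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts are also given with an absolute log2 fold change of at least 1. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The 5 comparisons were heat against control in wt, the same in hop, hop against wt at control, hop against wt under heat, and the difference between the responses of both genotypes (interaction). Values are given as mean normalized count ± SD, n = 3.

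Sets of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists within a comparison. They were tested again with a correlation estimated from the data, and with fry. A list's count of called members is given over all tested genes and adjusted over the list alone. The lists covered small heat shock proteins, the HSP70 family, the HSP90 and HSP100 families, organellar chaperonins, J-domain proteins and co-chaperones, heat shock factors, acquired thermotolerance, ER protein quality control, proteasome subunits, autophagy, photosynthesis, cytosolic ribosomal proteins and the cell cycle. They also covered salicylic acid and immune response, jasmonate, abscisic acid with osmotic and cold response, reactive oxygen, auxin, flavonoid synthesis, glucosinolate synthesis, the circadian clock and heat-activated ONSEN retrotransposons. Markers of root hairs, endodermis, the stomatal lineage, xylem and seed storage stood for other cell types. The ONSEN list had 0 of its 8 members in the table and gave no result.

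The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named HOP1, HOP2 and HOP3, then the 6 largest rises and 6 largest falls per comparison. Those had to be called with an absolute log2 fold change of at least 1, a mean CPM of at least 1, no overlap between the replicates of both groups (not asked of the interaction) and a gene symbol. It also named up to 4 called members of each list with the largest change, and 18 heat response genes whatever their result (HSFA2, HSP101, HSA32, HSP90.1, HSP70-4, HSP70b, HSP17.6C, HSP21, HSP22.0, ROF1, ROF2, DREB2A, MBF1C, BIP1, BIP2, BIP3, bZIP60 and APX2). Some of the genes it named are left out for length. Genes outside the rule are said to have been chosen after their values were seen.

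The limma test was tested on simulated counts drawn from the real means and depths for 23562 genes. Changed genes were taken from those with a mean of at least 10, and the simulated means held no effect of heat. In the comparison of genotypes under heat it recovered 78 of 100 genes simulated at a 2-fold change. At 4-fold it recovered 99 of 100, and it made 28 false calls in this comparison. These were a larger share of its calls than the threshold for a call is meant to allow. There edgeR with TMM recovered 75 and 97 of 100, with 17 false calls, also a larger share than meant. For the interaction limma recovered 51 and 91 of 100, with 10 false calls. In the 2 comparisons simulated without change it made 0 calls. Camera passed the raised list in the comparison of genotypes under heat and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so false list calls from correlated genes could not show there.

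Replicate numbers were checked for pairing by correlating deviations from group means between same-numbered libraries. At control, wt and hop libraries with the same number correlated at 0.314, 0.178 and 0.174, each above 0.1, so the numbers were taken to pair the genotypes at control, from the data alone. Under heat the correlations were 0.0559, 0.104 and 0.183, the first of them under 0.1, and the numbers were not taken as pairs. In both conditions each wt library correlated more with its same-numbered hop library than with the other hop libraries, so pairing under heat is left open. No pair of replicates had identical values, and the mean chi-square per gene between replicates was 12.1 to 102, so all 12 libraries were counted.

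Alternatives were other pseudocounts (0.1 and 5), other low-value filters, the compared groups alone, a replicate block, each library left out in turn, stricter thresholds, edgeR 4.0.16 on the recovered fragments with DESeq2's size factors or total library size, and DESeq2 1.42.0. The design named edgeR with TMM as the test for raw counts, and edgeR on recovered fragments as an added alternative for normalized values. It was therefore run on the recovered fragments with TMM too. Alternatives chosen after seeing the data were a replicate block within each condition, leaving out both control libraries numbered 1, and leaving out organellar genes. A correction of each library for a spline trend (4 degrees of freedom) on GC content and gene length, with and without that block, was also chosen then. The size factors of the deposited values rest on the median gene, whereas total library size does not. Scaling by library size alone moved the median of all genes by -0.88 (log2) for heat in wt, -0.92 for heat in hop, -0.09 and -0.13 for genotype at control and under heat, and -0.04 for the interaction. A TAIR10.1 annotation matched 32548 of the 32833 gene identifiers (99.1%). It was used for names, gene order, length and GC content, with no coordinates printed because the authors' build is not known, and 98.9% of tested genes had a length and GC content.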

Results

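Transcript levels were compared in 12 libraries from 7-day-old seedlings of wild-type Arabidopsis (wt) and of the hop1 hop2 hop3 triple mutant (hop), under control conditions or after 3 h at 38 °C. HOP proteins are co-chaperones that link HSP70 and HSP90. The design asks how seedlings of both genotypes respond to heat, and how the genotypes differ in each condition. Depth was 29.8 ± 3.93 M fragments in wt control, 28.4 ± 1.37 in wt heat, 31.9 ± 2.85 in hop control and 35.3 ± 3.31 in hop heat (SD, n = 3 each). Genes detected numbered 23537 ± 275, 22481 ± 136, 23626 ± 141 and 22769 ± 229 in the same order.

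The first principal component held 82.1% of the variance and separated control from heat, and the second, with 4.24%, separated the genotypes. The small heat shock protein, HSP70 and HSP90 with HSP100 lists together took 0.203% ± 0.0137 of fragments in wt control and 14.8% ± 1.14 in wt heat, against 0.223% ± 0.00766 and 14.5% ± 0.142 in hop. Chloroplast-encoded genes took 6.13% ± 1.44 in wt control, 5.09% ± 2.22 in wt heat, 7.45% ± 0.938 in hop control and 7.02% ± 2.13 in hop heat. Mitochondrially encoded genes took 0.235% ± 0.0546 and 0.799% ± 0.0708 in wt, and 0.287% ± 0.00998 and 1.15% ± 0.136 in hop, at control and heat respectively.

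The targeted genes were examined first. At control, HOP2 (AT1G62740) had a normalized count of 556 ± 76.5 in wt and 7.07 ± 0.664 in the libraries labelled hop1 hop2 hop3, 1.27% of the wt mean. HOP3 (AT4G12400) had 80.7 ± 6.92 in wt and 4.55 ± 4.70 in hop, 5.63% of wt. HOP1 (AT1G12270) was not lower, with 650 ± 98.6 in wt and 596 ± 69.6 in hop (log2 fold change -0.12, adjusted p = 0.917, limma). Under heat HOP3 rose to 111381 ± 19304 in wt and stood at 1272 ± 66.8 in hop, 1.14% of wt. HOP2 rose to 8002 ± 657 in wt and 4718 ± 587 in hop, so that the hop libraries reached 59.0% of the wt level. HOP1 stood at 1216 ± 197 in wt heat and 2068 ± 359 in hop heat.

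HOP2 was lower in hop in both conditions, by log2 fold changes of -6.10 at control (adjusted p = 1.02e-13, limma) and -0.77 under heat (adjusted p = 0.00199, limma). HOP3 was lower by -6.44 under heat (adjusted p = 0.00135, limma) and -4.43 at control (adjusted p = 0.0259, limma). The HOP3 call at control was lost in limma without wt control replicate 1 (adjusted p = 0.0642), 2 (0.105) or 3 (0.108), without hop control replicate 2 (0.0677), and with the replicate block (0.0508). Over all alternatives its adjusted p ran from 1.01e-24 with DESeq2 to 0.125. HOP1 was higher in hop under heat by 0.76 (adjusted p = 0.00869, limma), a call that ended when scaled by library size alone (0.63, adjusted p = 0.129 in edgeR, with 1.23e-04 the lowest over all alternatives). Values per gene do not show whether a transcript is full length. Because HOP1 went against the label, and HOP2 did so in part under heat, hop stands for the libraries labelled hop1 hop2 hop3 throughout.

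**Figure D1:**
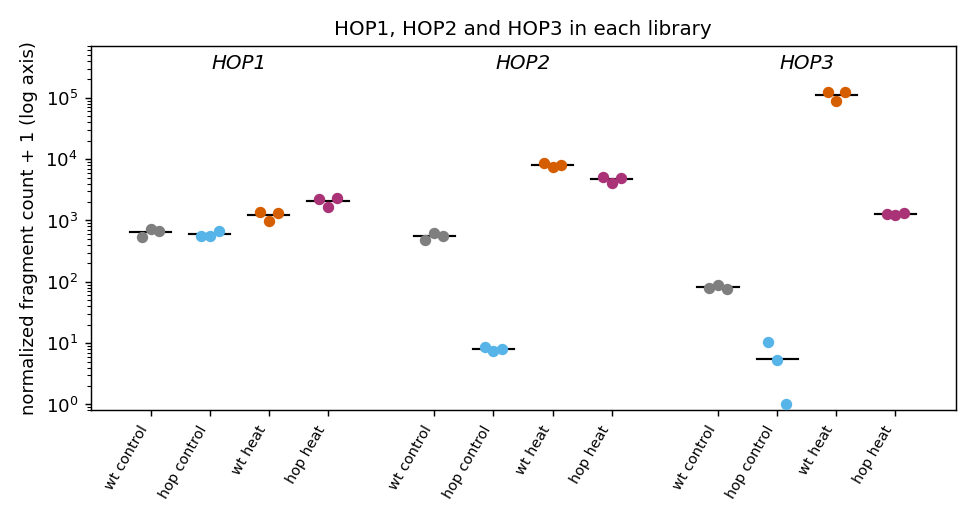
Normalized fragment count + 1 (log axis) of HOP1, HOP2 and HOP3 in each of the 12 libraries, with points for libraries and lines for group means (n = 3). HOP2 averaged 7.07 in hop control and 4718 in hop heat, against 556 and 8002 in wt, while HOP3 averaged 4.55 and 1272 in hop against 80.7 and 111381 in wt.

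Heat in wild-type seedlings raised chaperone transcripts from low levels. HSP23.6, a mitochondrial small heat shock protein, went from 6.74 ± 7.15 to 238306 ± 39339 (log2 fold change 15.44). HSP17.6C, a cytosolic one, went from 21.2 ± 18 to 487987 ± 27523 (14.76), and the chloroplast HSP21 from 3.94 ± 0.540 to 108956 ± 14823 (14.42). HSFA2, a heat shock factor that sustains the response, rose from 3.80 ± 3.14 to 60802 ± 4234 (13.84). HSP90.1 rose from 132 ± 17 to 456614 ± 7459 (11.75, adjusted p = 1.33e-18, limma), and HSP101, the disaggregase needed for thermotolerance, from 86.4 ± 7.20 to 266614 ± 24535 (11.57).

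Further large rises in wt were those of the ascorbate peroxidase APX2 (0.205 ± 0.355 to 51052 ± 5551), HSP17.6 (15.19), HSP22.0 (14.63), the co-chaperone ROF2 (11.71), HSP70b (11.33), HSP70-4 (11.17), the transcriptional co-activator MBF1C (9.51) and HSA32 (7.83). HOP3 rose by 10.40 and HOP2 by 3.85. HOP1 rose by 0.90 (adjusted p = 1.07e-04, limma), but by 0.03 when scaled by library size alone (adjusted p = 0.923 in edgeR, with 3.53e-07 the lowest over all alternatives). In the endoplasmic reticulum the HSP70 chaperones BIP1 and BIP2 rose by 4.31 and 2.99. BIP3 had a log2 fold change of -1.45 (adjusted p = 0.0911, limma), which passed without wt heat replicate 3 (adjusted p = 0.0117 in limma) and by library size alone (-2.08, adjusted p = 0.0280 in edgeR), over a range of 0.0117 to 0.328. bZIP60, a transcription factor of the unfolded protein response, rose by 0.53 (adjusted p = 0.00282, limma), and its direction flipped to -0.35 when scaled by library size alone.

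Among the largest falls in wt, FLS2, the receptor of bacterial flagellin, had 558 ± 109 at control and 0 in all 3 heat libraries, at least 395-fold lower. IAA29, an auxin response repressor, fell from 1240 ± 229 to 4.51 ± 2.56 (-7.93). PAR1, a regulator of shade responses, fell by 6.87 on the log2 scale from 2098 ± 293. The peroxidase PER4 had 89.9 ± 24 at control and 0 in all 3 heat libraries, at least 63.5-fold lower. GAT1_2.1 and SAUR22 fell by 7.51 and 6.39 on the log2 scale.

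Of 23827 genes tested in wt, 16435 were called, 7904 higher and 8531 lower under heat, and 9767 of these had an absolute log2 fold change of at least 1. Scaled by library size alone, 3172 were higher and 14504 lower, so that the share of higher calls was 17.9% in place of 48.1%. In 72.4% of all tested genes the replicates of both groups did not overlap, which chance gives for 10% of genes. The authors' deposited table gave an adjusted p under 0.05 to 15776 genes for this comparison.

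All 18 small heat shock protein genes rose in wt (median 13.46; 18 adjusted over the list alone), as did 13 of 14 of the HSP70 family (4.12; 14), 10 of 10 of the HSP90 and HSP100 families (5.34; 10) and 8 of 8 organellar chaperonins (3.23; 8). Their adjusted p in limma's camera was 6.75e-13, 3.71e-10, 8.46e-09 and 1.43e-05. These became adjusted p = 0.0725, 0.0409, 0.0409 and 0.105 with an estimated correlation. Of 18 J-domain proteins and co-chaperones 14 rose and 2 fell (median 4.21; 15 and 2 adjusted over the list alone), of 26 heat shock factors 18 rose and 3 fell (2.21), and of 13 acquired thermotolerance genes 12 rose (11.57). These 3 lists passed camera also with an estimated correlation (adjusted p = 0.0124, 0.0124 and 0.00707). In the endoplasmic reticulum list 23 of 32 rose and 2 fell (median 1.19, adjusted p = 1.92e-06 in camera), among them the J-domain protein ERDJ3A (7.81). That call was lost at adjusted p = 0.10 with an estimated correlation.

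Several other lists rose in wt with smaller medians. Cytosolic ribosomal protein genes rose in 16 of 19 cases and fell in 1 (median 0.93, adjusted p = 1.39e-05 in camera; 17 rising adjusted over the list alone), for example RPL3A (1.51). The abscisic acid, osmotic and cold response list had 16 of 22 rising and 3 falling (2.01, 1.72e-04), with the cold-induced KIN1 (3.96) and the dehydrin COR47 (3.87). Flavonoid synthesis genes rose in 7 of 12 cases (1.25, 0.0154), including the flavonol synthase FLS1 (3.31) and the chalcone synthase TT4 (2.39). With an estimated correlation the adjusted p of these 3 lists was 0.308, 0.269 and 0.306.

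The medians of 5 further rising lists in wt turned negative when scaled by library size alone. They were proteasome subunits (22 of 36 up, 2 down; median 0.34, -0.54 by library size), autophagy (12 of 16 up, 2 down, 13 up adjusted over the list alone; 0.55, -0.33), nuclear-encoded photosynthesis (26 of 38 up, 1 down; 0.41, -0.47), reactive oxygen (10 of 15 up, 2 down; 0.88, -0.00) and the circadian clock (8 of 13 up, 3 down; 0.87, -0.02). Relative to the shift of all genes under that scaling, their medians were 0.34, 0.55, 0.41, 0.88 and 0.86. In limma's camera their adjusted p was 6.60e-04, 0.00295, 0.00865, 0.0121 and 0.0218. This became adjusted p = 0.308, 0.226, 0.740, 0.226 and 0.432 with an estimated correlation. Large members were the proteasome subunit RPN6 (3.1), ATG8H of the autophagosome (3.32), the zinc finger regulators ZAT10 (4.29) and ZAT12 (3.59) and the morning clock gene CCA1 (3.51). The photosynthesis call also ended after the correction for GC content and gene length (median 0.16, adjusted p = 0.292 in camera).

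Lists that fell in wt were auxin response (15 of 19 down, 0 up; median -1.97, adjusted p = 2.32e-05 in camera), with IAA4 at -3.99, and cell cycle (21 of 29 down, 2 up; -0.79, 0.00446), with the mitotic cyclins CYCA1;1 (-4.62) and CYCB1;2 (-3.32). With an estimated correlation their adjusted p was 0.0744 and 0.323. Lists that did not pass camera in wt were glucosinolate synthesis (5 up, 10 down of 17; adjusted p = 0.0806), salicylic acid and immune response (5 up, 3 down of 19; 0.997) and jasmonate (5 up, 3 down of 14; 0.818). Among markers of other cell types, 2 of 6 root hair genes rose and 1 fell (0.891), 1 of 6 endodermis genes rose and 4 fell (0.112), 2 of 7 stomatal lineage genes rose and 2 fell (0.891), 4 of 10 xylem genes rose and 2 fell (0.891), and 0 of 10 seed storage genes were called (0.891). For all lists called in wt, the estimated correlation gave the highest adjusted p of all alternatives run.

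In hop the response to heat had the same leading genes. HSP21 rose from 5.72 ± 7.64 to 126863 ± 24079 (log2 fold change 14.84), HSP23.6 from 10.5 ± 9.39 to 257048 ± 49519 (14.72), HSP17.6C by 14.08 to 508115 ± 5903, and HSFA2 by 12.64 to 71397 ± 18674. HSP90.1 rose by 11.32 to 525851 ± 65066 (adjusted p = 2.33e-18, limma), HSP101 by 11.65 to 319451 ± 72091, and HSP70b by 11.94 to 369243 ± 70035. APX2 rose by 14.09, HSP22.0 by 14.63, ROF2 by 11.46, MBF1C by 9.26 and BIP1 by 4.1. BIP3 fell from 31 ± 18 to 4.96 ± 4.51 (-2.45, adjusted p = 0.00854, limma), and bZIP60 rose by 0.61 but had -0.31 when scaled by library size alone. The largest falls were those of IAA29 (1059 ± 367 to 3.83 ± 3.35, -8.15), FLS2 (471 ± 169 to 1.27 ± 0.215, -7.63) and PAR1 (-7.23).

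In hop 16326 genes were called, 7929 higher and 8397 lower under heat, with 9627 at an absolute log2 fold change of at least 1. Scaled by library size alone, 3111 were higher and 14734 lower (17% higher in place of 48.6%). The authors' deposited table gave an adjusted p under 0.05 to 15714 genes.

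The chaperone lists rose in hop as follows. Calls covered 18 of 18 small heat shock proteins (median 13.31), 14 of 14 of the HSP70 family (4.43), 10 of 10 of the HSP90 and HSP100 families (5.73), 8 of 8 organellar chaperonins (3.04) and 12 of 13 acquired thermotolerance genes (11.46). Of 18 J-domain proteins and co-chaperones 16 rose and 2 fell (4.33), of 26 heat shock factors 19 rose and 4 fell (2.71), and of 32 endoplasmic reticulum genes 22 rose and 3 fell (0.91; 23 and 3 adjusted over the list alone). All 8 passed camera, and in the order given their adjusted p with an estimated correlation was 0.0659, 0.0409, 0.0409, 0.115, 0.00709, 0.0114, 0.0135 and 0.104.

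Other lists that rose in hop were abscisic acid, osmotic and cold response (15 of 22 up, 3 down; median 1.97, adjusted p = 3.70e-05 in camera), with KIN1 at 4.06, and flavonoid synthesis (9 of 12 up, 1 down; 1.57, 0.00575). The circadian clock list had 8 of 13 up and 3 down (1.18, 0.0369), a call lost without hop control replicate 2 (0.0533). With an estimated correlation the adjusted p of these lists was 0.233, 0.237 and 0.490. Medians that turned negative when scaled by library size alone were those of ribosomal proteins (16 of 19 up, 1 down; 0.92, -0.01 by library size), proteasome (20 of 36 up, 2 down; 0.37, -0.55), autophagy (14 of 16 up, 2 down; 0.63, -0.29), photosynthesis (30 of 38 up, 1 down; 0.48, -0.44) and reactive oxygen (9 of 15 up, 4 down; 0.82, -0.09). Relative to the shift of all genes under that scaling (-0.92), their medians were 0.91, 0.37, 0.63, 0.48 and 0.83. In camera their adjusted p was 3.70e-05, 0.00129, 0.00129, 0.00336 and 0.0249, and adjusted p = 0.354, 0.354, 0.201, 0.687 and 0.249 with an estimated correlation. The photosynthesis call ended after the correction for GC content and gene length (median 0.24, adjusted p = 0.132 in camera).

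Auxin response genes fell in hop in 17 of 19 cases (median -1.93, adjusted p = 1.14e-05 in camera). Cell cycle genes fell in 17 of 29 cases and rose in 5 (-0.75, 0.0405), a call lost without hop control replicate 2 (0.0677) or hop heat replicate 1 (0.0586). The cell cycle call also ended after the correction for GC content and gene length (median -0.58, adjusted p = 0.0505 in camera). Endodermis markers fell in 4 of 6 cases (-2.09, 0.0343), a call lost without hop heat replicate 3 (0.0547). With an estimated correlation the adjusted p was 0.0659, 0.498 and 0.478. Lists not past camera in hop were glucosinolate synthesis (6 up, 9 down; 0.443), salicylic acid (7 up, 4 down; 0.797), jasmonate (6 up, 4 down; 0.443), root hair (2 up, 2 down; 0.797), stomatal lineage (3 up, 2 down; 0.797), xylem (5 up, 2 down; 0.484) and seed storage (0 called; 0.967). For all lists called in hop too, the estimated correlation gave the highest adjusted p of all alternatives run.

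Genotypes were next compared at control, where few genes differed. QQS, a gene that affects starch content, had 10.1 ± 2.96 in wt and 97.0 ± 21.9 in hop (log2 fold change 3.15, adjusted p = 0.00512, limma). LBD26 was higher in hop (15.9 ± 1.3 to 61.4 ± 4.22; 1.89), as were LEA7, a late embryogenesis abundant protein (38.8 ± 2.32 to 99.9 ± 14.7; 1.33), and the clock gene CCA1 (375 ± 12.3 to 659 ± 118; 0.80, adjusted p = 0.00213, limma). REV7, a DNA polymerase subunit, was lower (74.0 ± 7.70 to 8.11 ± 1.98; -3.06), as were ATG8G (165 ± 10.7 to 63.0 ± 3.63; -1.37) and ATG8D (189 ± 20.3 to 82.9 ± 5.0; -1.18), which encode ubiquitin-like proteins of the autophagosome. With HOP2, these 7 genes were those of the 21 named called genes that kept their call whichever library was left out. The calls of QQS and LBD26 ended without both control libraries numbered 1 (adjusted p = 0.0755 and 0.0531 in limma).

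HSP90.1 was higher in hop at control (132 ± 17 in wt, 204 ± 19.6 in hop; 0.63, adjusted p = 0.0218, limma), and so was the abscisic acid marker RD29B (103 ± 5.50 to 202 ± 18; 0.97, adjusted p = 0.0148, limma). In limma the HSP90.1 call was lost without wt control replicate 3 (0.141), hop control replicate 1 (0.0574) or 2 (0.112), with 0.00137 the lowest over all alternatives. The RD29B call was lost in limma without wt control replicate 2 (0.0586) or 3 (0.0615) or hop control replicate 1 (0.0589) or 2 (0.0588), over a range of 1.47e-04 to 0.138. Heat genes not called at control were HSP70-4 (0.61, adjusted p = 0.144), APX2 (1.52, 0.116), HSP101 (0.16, 0.853) and HSFA2 (1.39, 0.243, all limma). Same-numbered libraries paired at control, and HSP70-4 passed with the replicate block (adjusted p = 0.0311 in limma, 0.0256 in edgeR). In limma with the block within condition HSP70-4 (adjusted p = 0.00432), APX2 (0.0273) and HSP70b (-0.42, 0.0252) passed. With a library left out in limma, HSFA2 passed without wt control replicate 1 (1.89, adjusted p = 0.0201, range 0.0201 to 0.552 over all alternatives), HSP70-4 without the same library (0.0367), and APX2 without hop control replicate 3 (1.38e-04).

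At control 198 genes were called, 82 higher and 116 lower in hop, and 83 had an absolute log2 fold change of at least 1. Scaled by library size alone, 43 were higher and 167 lower (20.5% higher in place of 41.4%). With the replicate block edgeR called 515 genes, limma 274, and limma with the block within condition 680, of which 377 were higher and 303 lower, so that the majority direction turned. Fewer were called without wt control replicate 2 (69) or 3 (54), without hop control replicate 1 (93), 2 (101) or 3 (116), and without both control libraries numbered 1 (71). Replicates did not overlap in 18% of all tested genes, against 10% by chance. The authors' deposited table gave an adjusted p under 0.05 to 458 genes, and 184 genes were called in both in the same direction.

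Of the lists, 8 passed camera at control, 0 of them with an estimated correlation. Cytosolic ribosomal proteins were higher in hop (median 0.24, adjusted p = 1.78e-11 in camera) with 0 of 19 members called and 7 adjusted over the list alone. The abscisic acid, osmotic and cold response list was higher (0.35, 6.04e-04; 1 of 22 called, 6 adjusted over the list alone), as were organellar chaperonins (0.25, 0.00207; 0 of 8, and 1) and flavonoid synthesis (0.23, 0.00983; 1 of 12, and 3). With an estimated correlation each of these had adjusted p = 0.503.

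Acquired thermotolerance genes (median 0.16, adjusted p = 0.0113 in camera; 0 of 13 called, 1 adjusted over the list alone) and small heat shock proteins (0.26, 0.0144; 0 of 18, and 2) were higher in hop at control, with adjusted p = 0.503 and 0.725 with an estimated correlation. Without hop control replicate 1 the former had 0.298 in camera and the latter turned to -0.03 (0.789, the highest over its alternatives). The small heat shock protein call was also lost without wt control replicate 2 (0.136) or 3 (0.118). Cell cycle genes were lower (-0.17, 0.0144; 0 of 29 called, and 0 adjusted over the list alone), with adjusted p = 0.634 with an estimated correlation. That call was lost without wt control replicate 2 (0.310) or hop control replicate 3 (0.141).

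The autophagy list was lower at control (median -0.07, adjusted p = 0.0496 in camera; 1 of 16 up and 2 down) and had adjusted p = 0.634 with an estimated correlation and 0.0650 with the replicate block. It kept its call in 3 of the 12 fits with a library left out. It was lost without wt control replicate 1 (0.212) or 3 (0.124), hop control replicate 1 (0.102) or 2 (0.266), wt heat replicate 1 (0.0532), 2 (0.0506) or 3 (0.0574), and hop heat replicate 1 (0.0610) or 3 (0.0533). Its called members went both ways, with ATG8G and ATG8D lower and ATG8B higher (0.49). The circadian clock list did not pass (adjusted p = 0.0619 in camera), with CCA1 and LHY higher. The LHY call (0.64, adjusted p = 0.0107, limma) was lost without wt control replicate 3 (0.0834) or hop control replicate 1 (0.0566), over a range of 3.83e-05 to 0.0852. The ATG8B call (adjusted p = 0.0342, limma) was lost without wt control replicate 1 (0.0501), 2 (0.170) or 3 (0.0953), hop control replicate 1 (0.108), 2 (0.0877) or 3 (0.117), wt heat replicate 1 (0.0561) or hop heat replicate 1 (0.0553), with 0.00220 the lowest over all alternatives.

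**Figure D2:**
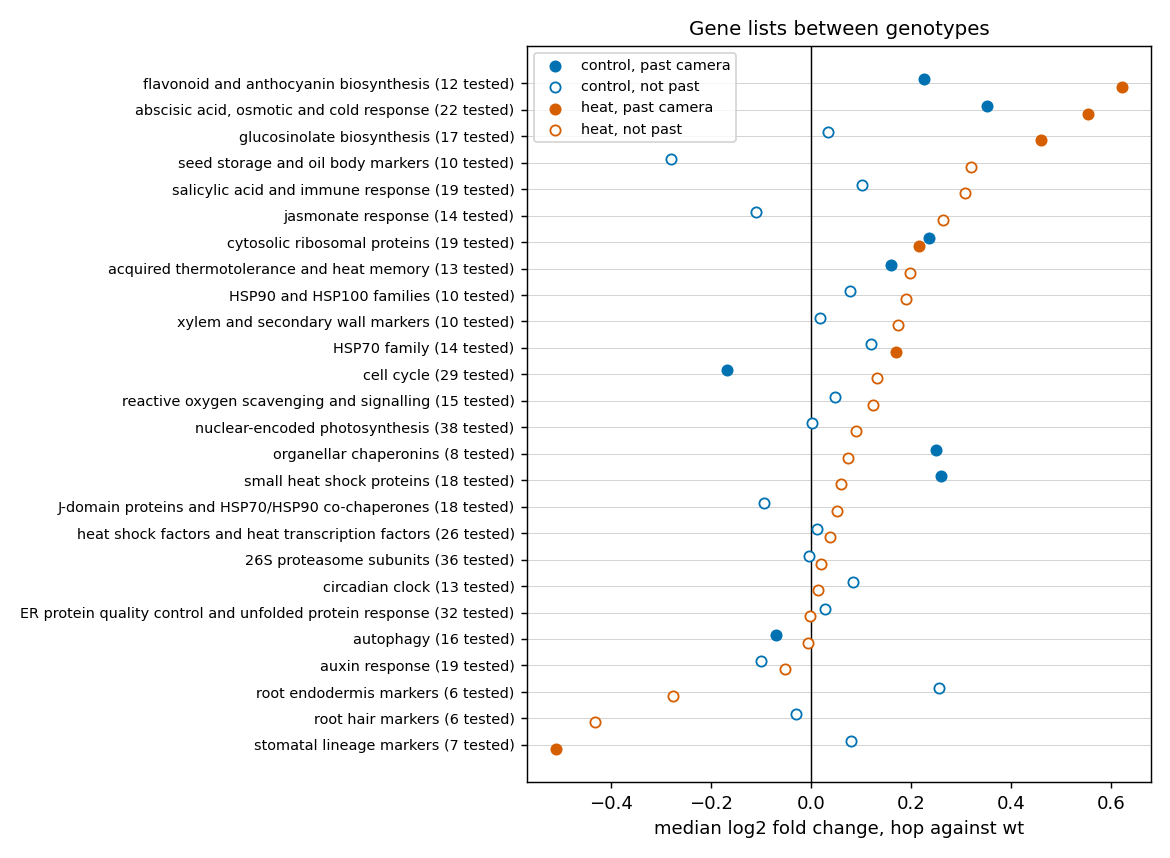
Median log2 fold change of hop against wt (x axis) over the tested members of each of 26 gene lists (y axis), at control (blue) and under heat (orange), with filled points for lists past camera at a preset correlation. Under heat the flavonoid, abscisic acid and glucosinolate lists stood at 0.62, 0.55 and 0.46, and no list passed with an estimated correlation. The medians of lists that turned when scaled by library size alone lay between 0.01 and 0.13 under heat and between 0.001 and 0.08 at control.

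Genotypes were then compared under heat, where some genes of abscisic acid response and of flavonoid and glucosinolate synthesis stood higher in hop. The abscisic acid marker RD29B had 396 ± 102 in wt and 1125 ± 201 in hop (log2 fold change 1.52, adjusted p = 1.67e-04, limma). ICL, an enzyme of the glyoxylate cycle, had 193 ± 66.0 and 584 ± 176 (1.61), JAZ10, a repressor of jasmonate signalling, 160 ± 23 and 331 ± 30.2 (1.05), and MAM1, a glucosinolate chain elongation enzyme, 936 ± 66.9 and 1699 ± 93.7 (0.86, adjusted p = 6.00e-04, limma). GDPD1, a glycerophosphodiester phosphodiesterase, was lower in hop (2205 ± 448 to 661 ± 49.4; -1.72, adjusted p = 8.24e-06, limma). The splicing factor RS31A (193 ± 37.6 to 60.8 ± 11.2; -1.65) and ATG8G (76.8 ± 13.7 to 21 ± 2.1) were lower as well. These calls held whichever library was left out, as did those of DAA1 (1.85), ZFWD4 (2.49), ATG8D (-0.73), CYP79F2 (2.35), and the flavonoid enzymes FLS1 (0.81) and F3H (0.80). The CYP79F2 call ended with a pseudocount of 0.1 (adjusted p = 0.0713 in limma), and in edgeR with TMM (0.0646), with DESeq2's size factors (0.0584) and by library size alone (0.0971). The ZFWD4 call ended with a pseudocount of 0.1 (adjusted p = 0.139 in limma).

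Of the 18 heat response genes named whatever their result, 0 were called between genotypes under heat. HSFA2 differed by 0.20 (adjusted p = 0.825), HSP101 by 0.24 (0.342), HSP90.1 by 0.20 (0.333) and HSP17.6C by 0.06 (0.977, all limma), and HSP101 passed without hop heat replicate 3 (0.0277). HSP70-4 had 0.20, HSP70b 0.18, HSP21 0.21, HSP22.0 0.21, APX2 0.21, HSA32 -0.20, DREB2A -0.13, BIP1 -0.16 and BIP2 0.07. BIP3 had an adjusted p of 0.860 in limma. In the tests on simulated data 78 of 100 genes at a 2-fold change were recovered in this comparison. Smaller differences, such as the 0.20 of HSFA2, were not simulated, so that rate does not show whether they would be found.

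Under heat 2053 genes were called, 889 higher and 1164 lower in hop, of which 543 had an absolute log2 fold change of at least 1. Scaled by library size alone, 209 were higher and 1042 lower (16.7% higher in place of 43.3%). With the block within condition limma called 4302, 2237 higher and 2065 lower, so that the majority direction turned. The count was 1180 without wt heat replicate 1, 1196 without wt heat replicate 3, 1079 without hop heat replicate 1 and 1133 without hop heat replicate 2. Replicates did not overlap in 25.9% of all tested genes, against 10% by chance. The authors' deposited table gave an adjusted p under 0.05 to 2202 genes, with 1747 called in both in the same direction. On simulated counts limma made a larger share of false calls in this comparison than the threshold is meant to allow. The 2053 calls may therefore hold more false ones than the threshold implies.

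Of the abscisic acid, osmotic and cold response list, 8 of 22 members were higher in hop under heat (11 adjusted over the list alone; median 0.55, adjusted p = 1.76e-05 in camera). Flavonoid synthesis had 5 of 12 higher (8 adjusted over the list alone; 0.62, 2.03e-04) and glucosinolate synthesis 5 of 17 (8; 0.46, 1.33e-04). Each of the 3 had adjusted p = 0.698 with an estimated correlation, the highest over their alternatives, and passed in all 12 fits with a library left out. Chalcone synthase TT4 (0.71, adjusted p = 0.0141, limma) lost its call without wt heat replicate 3 (0.0597) or hop heat replicate 1 (0.0665), and the cytochrome P450 CYP83A1 (0.69, 0.0160) without the same libraries (0.0690 and 0.0691). COR15A (1.23, 0.0207) lost its call without wt heat replicate 1 (0.0776) or 3 (0.0627) or hop heat replicate 2 (0.0777).

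Cytosolic ribosomal proteins were higher under heat as a list (median 0.22, adjusted p = 8.88e-04 in camera; 0 of 19 called, 0 adjusted over the list alone), with adjusted p = 0.838 with an estimated correlation and 0.0720 without hop heat replicate 1. The HSP70 family (0.17, 0.0313; 1 of 14, and 1) had adjusted p = 0.764 with an estimated correlation. It was lost without wt heat replicate 3 (0.127) or hop heat replicate 1 (0.178) or 2 (0.0575), and after the correction for GC content and gene length (median 0.125, 0.141). Stomatal lineage markers were lower (-0.51, 0.0420; 1 of 7, and 3), with FAMA, a guard cell regulator, at -0.51 (adjusted p = 0.0460, limma), and had adjusted p = 0.764 with an estimated correlation. They were lost without wt heat replicate 1 (0.186) or 3 (0.0755) or hop heat replicate 1 (0.0537) or 2 (0.229). They were lost after that correction too (0.0682), with the median still at -0.51. FAMA, the 1 called member, lost its call in limma without wt heat replicate 1 (0.131) or 3 (0.130), hop heat replicate 1 (0.0889) or 2 (0.160), or any 1 control library (0.0520 to 0.0676). The FAMA call was also lost after that correction (-0.47, adjusted p = 0.0504 in limma) and by library size alone (-0.62, adjusted p = 0.0947 in edgeR). Small heat shock proteins did not pass as a list (median 0.06, -0.08 when scaled by library size alone; adjusted p = 0.840 in camera), nor did the HSP90 and HSP100 families (0.19, 0.0803), which passed without hop heat replicate 3 (0.0180), with the replicate block (0.0361) and with the block within condition (0.0205), and had adjusted p = 0.816 with an estimated correlation and no block.

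**Figure D3:**
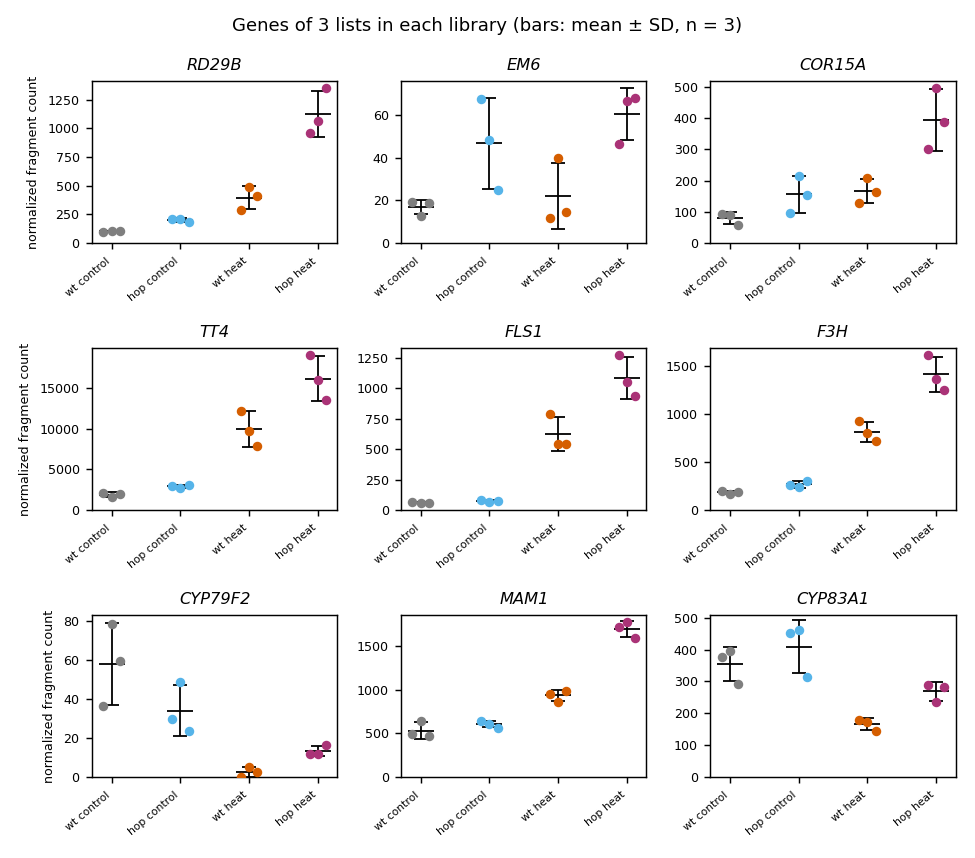
Normalized fragment count in each library (points) with mean ± SD (bars, n = 3) by group, for 3 genes each of the abscisic acid list (RD29B, EM6, COR15A), the flavonoid list (TT4, FLS1, F3H) and the glucosinolate list (CYP79F2, MAM1, CYP83A1). All 9 were higher in hop under heat, such as RD29B with 1125 ± 201 against 396 ± 102, while the calls of EM6, COR15A, TT4 and CYP83A1 depended on single libraries and that of CYP79F2 on the pseudocount and the test. In edgeR by library size alone EM6 (adjusted p = 0.0525) and CYP83A1 (0.0714) were not called, nor was EM6 in edgeR with the replicate block (0.0524).

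The genotypes' lists of called genes were compared across conditions, which share no library. Of the genes higher in hop, 45 were called in both conditions against 3.06 for independent lists, and of those lower, 77 against 5.67, with 1 called in opposite directions. Both comparisons take the spread of each gene from the same fit, so the lists are not independent and these numbers are a description. Among the 2053 genes called under heat, 80.5% had the same sign at control, and among the 198 called at control, 95.5% had the same sign under heat.

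The response to heat itself was last compared between genotypes. HOP2 rose more in hop, by 9.19 against 3.85 on the log2 scale (difference 5.34, adjusted p = 1.27e-10, limma). GDPD1 rose by 1.94 in wt and 0.59 in hop (-1.35, adjusted p = 0.0169, limma). SHM7, a serine hydroxymethyltransferase, also rose less in hop (-1.19, adjusted p = 0.0219, limma). None of HSFA2 (-1.20, adjusted p = 0.588), HSP70b (0.60, 0.262), HSP90.1 (-0.43, 0.403), HSP101 (0.08) and APX2 (-1.31, 0.446) passed in limma. HSP70b passed with the block within condition (adjusted p = 0.0335 in limma, and 0.0351 with the correction for GC content and gene length added) and without hop heat replicate 3 (0.0472), and APX2 without hop control replicate 3 (0.0160). The APX2 difference rests on control values of few fragments. HOP1 (0.88, 0.149) and HOP3 (-2.01, 0.571) did not pass in limma either, but HOP1 passed in limma with the block within condition (adjusted p = 0.00779, and 0.00611 with that correction added) and in DESeq2 (0.0301), and HOP3 passed without hop control replicate 3 (-2.97), over a range of adjusted p from 2.19e-04 to 0.946.

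In all 12 genes passed the interaction, 3 higher and 9 lower, with 2276 at an unadjusted p under 0.05. Scaled by library size alone the split was 1 and 4, with edgeR's TMM 3 and 31, and with DESeq2's size factors in edgeR 3 and 19. Chosen after their values were seen, the other 9 were lower for the transcription factor BHLH114 (-3.29), AT1G61300 (-1.35), AT2G40980, AT5G15270 (-1.0), CSN5B of the COP9 signalosome (-0.86), HAM1 (-0.83) and the nitrate reductase NIA2 (-0.80), and higher for AT4G20350 (1.34) and PCMP-E88 (3.14). BHLH114 had 5.62 ± 2.07 in wt heat and 0 in hop heat, and PCMP-E88 had 0 in wt heat and 8.51 ± 1.61 in hop heat. The size of both differences therefore depends on the pseudocount. The count was 5 without wt control replicate 2, 1 without wt control replicate 3, 4, 3 and 4 without wt heat replicates 1, 2 and 3, 2 and 5 without hop control replicates 1 and 2, and 5, 5 and 94 without hop heat replicates 1, 2 and 3. In the tests on simulated data 51 of 100 genes at a 2-fold difference were recovered.

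In limma the GDPD1 interaction was lost without wt control replicate 3 (0.0672), wt heat replicate 1 (0.0579) or 2 (0.0527), hop control replicate 1 (0.0567) or hop heat replicate 2 (0.0520), over a range of 5.52e-07 to 0.102. The SHM7 interaction was lost without wt control replicate 3 (0.101), wt heat replicate 1 (0.0579), 2 (0.0605) or 3 (0.0820), hop control replicate 1 (0.0567) or 2 (0.0623), or hop heat replicate 1 (0.0645) or 2 (0.0740), over a range of 2.70e-06 to 0.102.

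Across all 23827 tested genes the response in hop followed that in wt with a slope of 0.961 (jackknife SD 0.0234), a Pearson correlation of 0.955 and a Spearman correlation of 0.934, across genes that are not independent replicates. Among 14561 genes called in both genotypes 99.9% had the same sign and the slope was 0.990. The small heat shock protein list had a median difference of -0.27 (range -0.92 to 0.74, 14 of 18 below 0; adjusted p = 0.0663 in camera, and 0.747 with an estimated correlation). Its jackknife SD was 0.504, larger than the difference itself. Between genotypes the median of this list was 0.26 at control and 0.06 under heat. The median difference ran from -0.61 without wt control replicate 1 (3.58e-04) to 0.03 without hop control replicate 1 (0.903), and passed also without wt heat replicate 3 (0.0459) and hop control replicates 2 (0.00899) and 3 (0.00766). It passed with the replicate block (adjusted p = 0.0382 in camera) and with the block within condition (0.00338) too.

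Of the lists, glucosinolate synthesis (median 0.39, adjusted p = 8.76e-05 in camera; 0 of 17 called, 3 adjusted over the list alone) and the cell cycle (0.35, 0.00786; 0 of 29, and 0) differed in response between genotypes. Both had adjusted p = 0.745 with an estimated correlation, the highest over their alternatives. The cell cycle call was lost without wt control replicate 2 (0.0820), wt heat replicate 2 (0.0588) or hop heat replicate 3 (0.0504). With the block within condition, 4 more lists beside small heat shock proteins passed camera. Each had adjusted p = 0.745 in camera with an estimated correlation and no block. They were jasmonate (0.28, adjusted p = 0.0381, and 0.0463 with the replicate block in camera), abscisic acid (0.20, 0.0152), and the markers of root hairs (-0.42, 0.0381) and endodermis (-0.36, 0.00464).

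**Figure D4:**
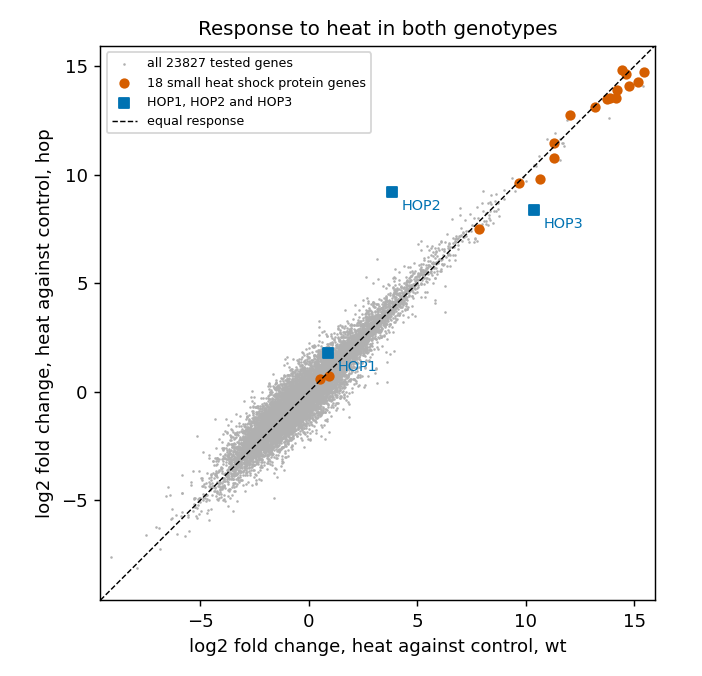
Log2 fold change of heat against control in hop (y axis) against that in wt (x axis) for 23827 tested genes (grey), with 18 small heat shock protein genes (orange), HOP1, HOP2 and HOP3 (blue squares), and a dashed line of equal response. HOP2 lay at 3.85 in wt and 9.19 in hop and HOP3 at 10.40 and 8.39, while the slope over all genes was 0.961.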

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

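Both tests of the HOP2 reads given here were chosen only after the result was seen, and the block within condition was added after seeing the data. Results are listed because a test of the difference between the genotypes' responses to heat passed. The response differed in 12 genes. Among the genes named by rule these were HOP2 (5.34, log2), GDPD1 (-1.35) and SHM7 (-1.19), with limma adjusted p of 1.27e-10, 0.0169 and 0.0219. Of the gene lists, the cell cycle (median 0.35) and glucosinolate synthesis (median 0.39) passed camera. Neither passed with an estimated correlation (adjusted p = 0.745 for each).

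The count of 12 genes was set against relabellings of genotype within each condition, of which 100 of 200 distinct ones were drawn, the real one included, and 6 called as many genes or more. The 5 others, the highest with 462 genes, all kept the heat groups together and mixed the genotypes at control. They therefore hold the genotype difference under heat (2053 genes called) and are no null for the interaction, so that chance is left open for this count. With the replicate block within condition the count was 385.

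HOP2 in the hop libraries under heat stood at 4718 ± 587 (n = 3), after 7.07 ± 0.664 at control. Reads of HOP1 or HOP3 assigned to HOP2 are argued against, because the lowest hop heat library held 32.9 times the largest value those reads could give at the rates the table allows. Wild-type material in the hop heat libraries is argued against too: HOP2 stood at 50.6% to 64.1% of its wt level there and HOP3 at 1.09% to 1.21%, a ratio of at least 46.3. The genotype remains as an open explanation, in which a disrupted HOP2 copy may still give heat-induced transcripts that HOP2 counts pick up. This is a hypothesis, since gene-level values do not show which part of the gene the reads came from.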

How the results depend on the processing

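Tests added after seeing the data were the replicate block within condition, the corrections for GC content and gene length, both control libraries numbered 1 left out, and organellar genes left out. With a library left out, 277 of 324 results of named genes and 101 of 130 list results kept their direction and side of the threshold in every fit, and under the other settings 265 and 73 did so. Where results moved, the cause was not tested, except that fewer genes pass a stricter threshold by construction. Of simulated 2-fold changes, 78 of 100 were recovered between genotypes under heat and 51 of 100 in the interaction. Between genotypes under heat limma made 28 false calls there, a larger share than the threshold is meant to allow. Counts by heat kept within 1.5 times of the reported ones except at an absolute log2 fold change of at least 1 (9767 in wt, 9627 in hop). With 1 library left out they ran from 15428 to 16641 in wt and 15315 to 16451 in hop.

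The count at control (198) became 82 with the compared groups alone, 83 at an absolute log2 fold change of at least 1, 53 at FDR under 0.01, 305 with edgeR's TMM, 448 with DESeq2, 71 without both control libraries numbered 1, and 54 to 214 with 1 library left out. The count under heat (2053) became 543, 643 and 1251 at the fold minimum, at FDR under 0.01 and by library size, and 1079 to 2334 with 1 library left out. The interaction count (12) became 26 with a pseudocount of 0.1, 3 at FDR under 0.01, 34 with TMM, 22 with DESeq2's size factors, 5 by library size, 182 with DESeq2, 30 after the correction for GC content and gene length, 3 without both control libraries numbered 1, and 1 to 94 with 1 library left out. Of the genes called at control, 49 of 198 were called in all 12 such fits, and of those called under heat 711 of 2053.

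By the rule of correlations above 0.1, replicate numbers paired the genotypes at control but not under heat. Each wt heat library still correlated most with its same-numbered hop heat library, so pairing under heat is left open. With the replicate block, edgeR called 515 genes at control and 175 in the interaction, and limma 34 in the interaction. With the block within condition limma called 680 at control, 4302 under heat and 385 in the interaction, and with the correction for GC content and gene length added 811, 4453 and 451. HOP3 at control lost its call in limma with the block (-4.43, adjusted p = 0.0508), with the block within condition (-4.43, 0.0520) and with the correction added (-4.40, 0.0534). The small heat shock protein difference passed camera with these 3 fits (-0.27, 0.0382; -0.27, 0.00338; -0.27, 0.00487). HOP1 passed the interaction in limma with the block within condition (0.88) and with the correction added (0.87), and in DESeq2 (0.89). With the replicate block in camera 18, 19, 7, 7 and 4 lists passed in the 5 comparisons, and the block turned no other call named for the HOP genes.

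HOP3 at control was past the threshold in 20 of 29 alternatives, lost also with a pseudocount of 0.1 (-5.65) and with the compared groups alone (-4.43), and ran from -5.15 to -3.47 with 1 library left out. HOP3 passed the interaction with a pseudocount of 5 (-3.14) and with DESeq2 (-2.17), and ran from -2.97 to -1.28. By library size HOP1 lost its calls for heat in wt (0.0263) and for genotype under heat (0.63). The small heat shock protein difference ran from -0.61 to 0.0261.

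The number of lists past camera (18, 19, 8, 6 and 2) fell to 5, 5, 0, 0 and 0 with an estimated correlation, and fry passed 0 at control, 3 under heat and 0 in the interaction. At control 5 passed with the compared groups alone. Under heat 3 to 7 passed with 1 library left out. In the interaction 4 passed at a mean of at least 10, 5 at a CPM of at least 1, 4 with the replicate block, 7 with the block within condition, 9 with the correction added, and 2 to 7 with 1 library left out.

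The slope of responses in hop on wt (0.961) was 0.894 and 0.985 with pseudocounts of 0.1 and 5, 0.987 with a CPM of at least 1, 0.905 with TMM, 0.904 with DESeq2's size factors, 0.907 by library size, 0.904 with edgeR's replicate block and 0.929 with DESeq2. In the same order the Pearson correlation (0.955) was 0.903, 0.972, 0.978, 0.909, 0.909, 0.915, 0.909 and 0.926, with 0.975 at a mean of at least 10 and 0.948 to 0.953 with 1 library left out. The Spearman correlation (0.934) was 0.901, 0.954, 0.971, 0.911, 0.911, 0.912, 0.911 and 0.914, with 0.918 without a filter, 0.966 at a mean of at least 10, and 0.923 to 0.931 with 1 library left out.

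By library size the fold of 9 called results changed sign. In the new direction edgeR called XCP1 (adjusted p = 0.0175) and bZIP60 (0.00905) in wt and bZIP60 in hop (0.0195), and the others were not called. For heat in wt these were RPT3 (-0.00386), SPCH (-0.0448), XCP1 (-0.39) and bZIP60 (-0.35), and in hop RHD6 (-0.0524), MYB60 (-0.0940), SPCH (-0.28), XCP1 (-0.27) and bZIP60 (-0.31). The small heat shock protein list at control changed direction without hop control replicate 1, where it was not called, and its median ran from -0.0280 to 0.498 with 1 library left out.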

Other observations

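Gene classes formed from annotation words (39 scanned, adjusted over all) and the tests of size factors, of the block within condition, of linkage and of mislabelling were chosen only after the results were seen. Subunits of the COP9 signalosome, a complex that removes NEDD8 from ubiquitin ligases, were lower in hop under heat in 6 of 10 cases (median -0.47, adjusted p = 3.71e-07 in camera, and 0.0460 with an estimated correlation). CSN5B went from 343 ± 19.1 in wt heat to 171 ± 14.2 in hop heat (log2 fold change -1.0), CSN6A from 521 ± 36.3 to 300 ± 34.1 (-0.80), and CSN1 fell by 0.76, with CSN8, CSN4 and CSN3 at -0.48, -0.46 and -0.42. At control 0 were called (median -0.15, adjusted p = 0.00322 in camera, and 0.168 with an estimated correlation). Their response to heat differed between genotypes (median -0.34, adjusted p = 3.39e-04 in camera, and 0.213 with an estimated correlation). Genes with a cystatin domain, found in inhibitors of cysteine proteases, were lower in hop in 3 of 6 cases at control (median -1.05, 4.53e-11, and 0.0217 with an estimated correlation) and in 4 of 6 under heat (-1.55, 3.71e-07, and 0.0460). AT5G05060 went from 534 ± 41.7 to 118 ± 8.85 at control (-2.17) and differed by -1.93 under heat. Late embryogenesis abundant genes were higher in hop at control in 6 of 63 cases (adjusted p = 7.08e-06 in camera, and 0.0460 with an estimated correlation).

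Genes of the mitochondrial genome rose with heat in wt in 115 of 136 cases (median 3.84, adjusted p = 1.11e-21 in camera, and 0.12 with an estimated correlation), with NAD6 at 8.03. Under heat 12 of 136 were higher in hop (0.50, 7.45e-07, and 0.388), as were 18 of 132 of the chloroplast genome (0.70, 1.50e-14, and 0.388). The mitochondrial share of fragments went from 0.235% in wt control to 0.799% in wt heat. Whether the mRNA kit captured organellar transcripts alike in all groups was not tested. Pentatricopeptide repeat genes, whose products act on organellar RNA, fell with heat in wt in 246 of 436 cases and rose in 83 (median -0.83, adjusted p = 0.00740 in camera, and 0.511 with an estimated correlation). Disease resistance genes fell in 73 of 124 cases and rose in 24 (-0.82, 0.00516, and 0.467). Next to HOP2 on the chromosome, AT1G62730 was higher in hop by 1.23 at control (adjusted p = 4.02e-04, limma) and 1.80 under heat (8.24e-06). Within 5 genes of a HOP gene, bVPE near HOP2 (0.79, adjusted p = 0.0160), AT4G12410 near HOP3 (1.72, 0.0151) and AT1G12300 near HOP1 (-0.99, 0.0262, all limma) were called under heat only. The other tested neighbours were called in neither condition.

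More genes were called between genotypes under heat (2053) than at control (198), 10.4 per gene called at control. Over the alternatives this ran from 4.65 in edgeR with the replicate block to 30.0 without wt control replicate 3, with 4.87 in DESeq2. Depth is argued against as the cause, because effective depth was lower under heat (mean size factors 0.707 in wt and 0.804 in hop) than at control (1.37 in both), with the highest heat library at 0.884 times the lowest control library. Thinning to equal effective depth took most from the control libraries and is no test of this, with 7.86 the lowest of 5 draws. Deviations shared by same-numbered libraries are argued against as the whole cause, with 6.33 under the block within condition. So is a trend with GC content and gene length, with 5.49 after its correction in the same fit. Both values lie below 10.4, so a part in the pattern is left open. A stronger difference between the genotypes under heat may lie behind the count as a hypothesis, and the test of the difference itself passed for 12 genes in limma, 385 with the block within condition, 175 in edgeR with the replicate block and 182 in DESeq2. For 3 libraries against 3, the 10 splits are too few for a share under 0.05: the real split was the 1 with most calls for heat in wt (16435, highest other 0), heat in hop (16326, 0), genotype at control (198, 9, and 0 among the splits that part all pairs) and genotype under heat (2053, 1).

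Of the genes that differed between genotypes, 122 did so in the same direction in both conditions. Tight clusters of these genes, as short linked segments would give, are argued against for the set. Among them 5 pairs lay within 10 genes of each other, and 450 of 1000 random sets had as many (median 4, 95th percentile 8). Longer segments that differ between the lines, with few of these genes far apart, would not show within 10 genes and are left open. A mislabelled library is argued against, because the lowest wt library exceeded the highest hop library in HOP2 and HOP3 in both conditions by at least 1.43 times. What stays open is the genotype, and differences between the lines at single loci or in longer linked segments. A constant effect of the genotype may account for these genes as a hypothesis.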
